A study of Mus musculus with 2 samples.

How the data were processed

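The samples were 2 droplet-based single-cell RNA libraries of ciliary epithelium from wild-type C57BL/6 mice at postnatal day 35, made from pooled tissue of 3 sets of eyes (library 1) and of 3 or 4 sets, as the labels differ (library 2). The authors deposited, for each library, a matrix of raw UMI counts per gene and cell barcode with the matching lists of barcodes and genes, and the header of each matrix names Cell Ranger 3.1.0. Per the labels, CASAVA 1.8, Cell Ranger and Seurat were used with the builds mm10 and GRCm38, with neither the role of each nor the annotation release stated. A further deposited matrix of counts per library held the same values, with 0 entries differing. The other deposited files, with barcodes and gene names, hold no measurements. The deposited counts were not normalised, held 33456 genes and had a minimum of 500 UMIs per barcode. Gene positions came from a GENCODE annotation of GRCm38, in which 32655 of the 33456 identifiers were found, and this need not be the annotation the authors used.

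Cells with at least 500 detected genes and at most 30% mitochondrial UMIs were kept. Scrublet, run per library with 5% of doublets assumed, marked 4 and 0 cells, so it has not worked and doublets were in effect kept. Library 1 retained 3861 of 4764 barcodes and library 2 retained 5466 of 6220. Genes were split at random (seed 1) into a clustering group of 16684 genes, which held all marker genes, and a held-out group of 16772 genes, which held all genes of the tested lists. No tested gene thus took part in forming the classes. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 highly variable genes of the clustering group were scaled to at most 10 and reduced to 30 principal components, and cells were clustered on 15 neighbours with the Leiden method at resolution 1 (scanpy 1.11.5, Python 3.11.15, igraph 0.11.9). Both libraries were clustered together without integration. Clusters were named from 172 marker genes of 30 cell types and of cycling cells. A marker counted if its mean was at least 0.5 per 10000 UMIs and at least 4 times the median over the other clusters, at least 3 had to count, and the type with the most markers among the 10 genes of largest fold gave the name. A pigmented cluster became retinal pigment epithelium if Rpe65, Rgr and Rdh5 counted, and melanocyte if Mlana, Kit and Sox10 counted without both Krt8 and Krt18. The markers were fixed in advance, but this scoring rule was not: it was written after the marker levels of the clusters had been seen. A fold against all other cells, looked at first, would have left the pigmented epithelium unnamed, since melanocytes and retinal pigment epithelium share its pigment genes. The rule was then revised 2 times, each time because the pigmented epithelium lacked a name under some alternatives. The first revision limited the melanocyte name to clusters with its 3 own genes, and the second left globin genes out of the leading genes. No alternative varied the rule itself.

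Counts were summed per class and library. The 18 classes with at least 20 cells in each library gave 36 sums, which entered 1 fit with class and library as terms (edgeR 4.0.16 in R 4.3.3, TMM normalisation, filterByExpr, quasi-likelihood F test, 17 residual degrees of freedom, common dispersion 0.0478). Retinal ganglion cells, with 15 cells in library 1, were left out of the fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1 over the 6991 held-out genes that passed the filter. At an unadjusted p under 0.05, 1292 genes differed between the epithelial layers. The median log2 fold change over all tested genes was -0.01 for the layers and 0.06 for fibroblasts against epithelium. Library was the replicate block, and the other classes supplied the residual spread, which assumes that the epithelial classes vary between pools like the rest. The 16 gene lists, with 323 genes, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists. The fit was tested on counts simulated from its own means and dispersions: of 100 genes changed 4-fold, 74% were recovered, of 100 changed 2-fold, 12%, and 3 of 89 called genes were unchanged ones. The changed genes were drawn only among held-out genes above a minimum mean count in the 2 epithelial classes. Recovery over all tested genes may therefore be lower.

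The comparisons, lists, cell filter, calling threshold and the rule for named genes were likewise set in advance. The rule took the 10 genes with the largest fold change in each direction among called genes with the same direction in both libraries and at least 50 UMIs in the higher class of each library, leaving out predicted, RIKEN, mitochondrial and ribosomal genes. It added up to 4 called members of each list per direction with the same UMI minimum, 3 genes per class against the other classes, and the 4 members of the drug and glaucoma lists with the most UMIs. Of the 582 genes called between the layers, 280 met the UMI minimum, and 18 had 0 UMIs in the lower class. Ratios against a class with 0 UMIs were computed against a floor of 3 counts over both libraries. Ratios against 1 to 3 UMIs are given with their 95% counting interval. Shares of cells carry exact Clopper-Pearson 95% intervals (scipy 1.17.1). Intervals and floors cover counting error only. Free RNA in the droplets adds UMIs of abundant genes to all cells, and expression values were not corrected for it.

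Alternatives were RLE size factors, no count filter, no replicate block, the DESeq2 Wald test (version 1.42.0), no fold change minimum, a fit of the compared classes alone, each library left out, doublets kept, mitochondrial limits of 15% and none, at least 1000 genes per cell, Leiden resolutions 0.5 and 2, clustering on all genes or by library, and count splitting. Added after seeing the data were the removal of the top 5% of Scrublet scores, count splitting at resolution 2, and the pigmented class without its Myh11-rich sub-cluster, found by clustering that class again.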

Results

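Droplet-based single-cell RNA sequencing was carried out on ciliary epithelium dissected from wild-type C57BL/6 mice at postnatal day 35. The series is exploratory and holds 2 libraries of 1 group, with no treatment. Library 1 pooled 3 sets of eyes. For library 2 the labels state 3 sets in 1 field and 4 in another, which the files do not settle. Each library is a single pool, so n = 2 libraries for every value, and the libraries were set side by side as repeats without a test between them. Library 1 held 4764 cell barcodes and 22510387 unique molecular identifiers (UMIs), and library 2 held 6220 barcodes and 30683405 UMIs. After filtering, library 1 retained 3861 cells with a median of 4128 UMIs and 1750 detected genes, and library 2 retained 5466 cells with a median of 2968 UMIs and 1481 genes. Chromosome positions below are those of the mouse build GRCm38.

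The question of this part was which cell types the dissection held. Clustering gave 25 clusters, which marker genes fixed before the data were examined assigned to 19 classes. The rule that turned markers into names was written after the clusters had been seen and was revised 2 times because the pigmented epithelium went unnamed under some alternatives. A class name therefore stands for a marker profile and not for a histological identification. Non-pigmented ciliary epithelium made up 3.57% of library 1 (138 cells, exact Clopper-Pearson 95% interval 3.01% to 4.21%) and 2.52% of library 2 (138 cells, 2.13% to 2.98%). Pigmented epithelium made up 3.47% (134 cells, 2.92% to 4.10%) and 3.90% (213 cells, 3.40% to 4.44%). The fibroblast class took 25.8% of library 1 (24.5% to 27.3%) and 10.2% of library 2 (9.45% to 11.1%). Trabecular meshwork markers also reached the naming minimum of 3 in its clusters of 353 and 154 and of 353 and 347 cells. Corneal stroma markers did so in its cluster of 292 and 59 cells. The smooth muscle class took 7.93% (7.09% to 8.82%) and 1.52% (1.21% to 1.88%). Of it, 37 of 306 and 16 of 83 cells held a Myh11 UMI. Fibroblast markers also reached the minimum there, and Dcn was among its leading genes. Cells of the neural retina together, from rods to Muller glia, made up 24.5% of library 1 (23.2% to 25.9%) and 63.6% of library 2 (62.3% to 64.9%), and rods alone 10.0% and 32.7%. Melanocytes accounted for 8.55% and 3.48%, retinal pigment epithelium for 5.67% and 4.37%, and macrophages, a class that here also holds mast cells and cells rich in class II histocompatibility genes, for 11.4% and 5.36%. The intervals cover the counting of cells only, not differences in dissection, and each share depends on what else was recovered. Across genes, the summed expression of a class in library 1 and library 2 had a Pearson r between 0.300 in neutrophils and 0.961 in fibroblasts, and it was 0.916 in non-pigmented and 0.939 in pigmented epithelium (Spearman coefficients 0.927 and 0.941). Genes are not independent replicates, so no p is given for these.

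**Figure D1:**
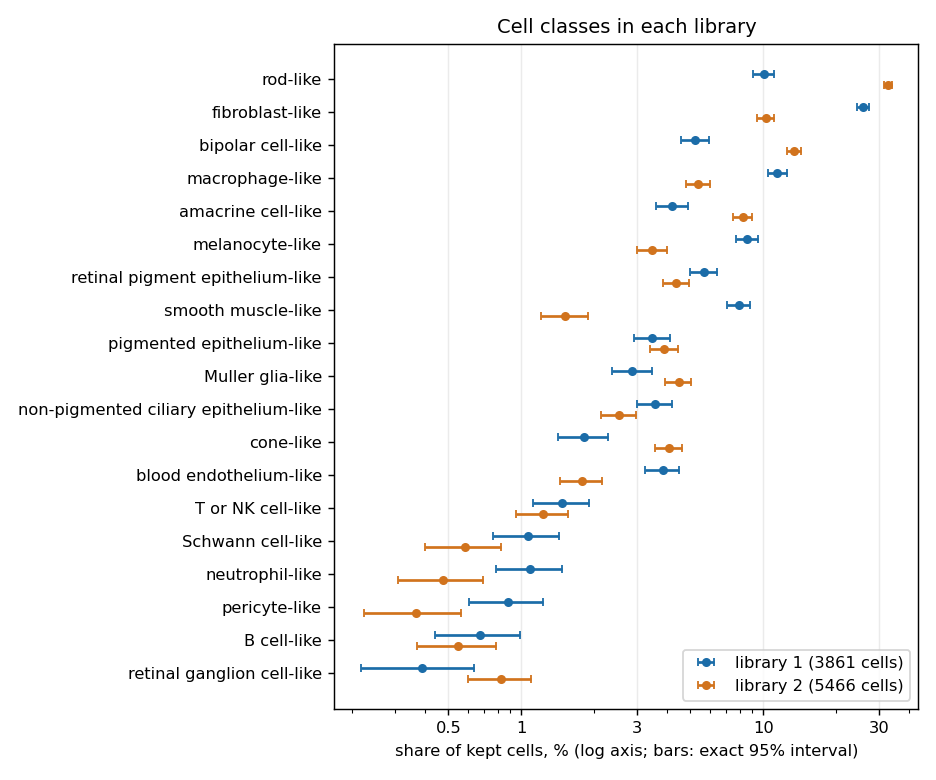
Share of kept cells in each class and library, in % on a log axis, with exact 95% binomial intervals as bars. The non-pigmented and pigmented epithelial classes lie between 2.52% and 3.90% in both libraries, whereas rods make up 10.0% of library 1 and 32.7% of library 2.

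The comparison of the non-pigmented with the pigmented class asks how the layers of the ciliary bilayer differ in expression. No marker was set to tell ciliary from iris epithelium, so the pigmented class may hold iris cells. Layer means the class below. Values of 1 library alone are differences of log2 CPM with a prior count of 2, without a fit. In library 1 the pigmented class had 0 UMIs of Tmem132b, Col2a1 and Pdyn and 1 of Aqp4. The prior count therefore largely set their values and ranks there. Ltbp2 had the largest excess in non-pigmented epithelium among the named genes in the fit over both libraries. In library 1 alone (5.02) it lay behind Cp, Tmem132b, Col2a1, Aqp4, Wfdc1, Pdyn, F5 and Aldh1a1 (6.71 to 5.10). This microfibril-bound protein (gene identifier ENSMUSG00000002020, chromosome 12, 84783212 to 84876532) stood at 254 and 265 CPM (UMIs of a gene per 1e+06 UMIs) in the non-pigmented class of library 1 and library 2, against 6.44 and 1.40 in the pigmented class, a log2 fold change of 6.25 ± 0.61 (SE). Pdyn, the precursor of the dynorphin opioid peptides (ENSMUSG00000027400, chromosome 2, 129686565 to 129699844), followed at 6.02 ± 0.73, with 85.9 and 129 CPM against 0 and 2.79. Wfdc1 reached 5.98 ± 0.50, the ferroxidase ceruloplasmin (Cp) 5.29 ± 0.54, and Tmem132b 5.22 ± 0.56. Next came the Notch ligand Dll1 (5.16), the collagen gene Col2a1 (4.95), coagulation factor V (F5, 4.66), the sulfate transporter Slc13a4 (4.52) and the water channel Aqp4 (4.50).

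In the other direction, Hs3st1, a heparan sulfate sulfotransferase (ENSMUSG00000051022, chromosome 5, 39613935 to 39755475), had the largest excess in pigmented epithelium among the named genes in the fit over both libraries, with 102 and 55.2 CPM there against 1.21 and 3.88 CPM in the non-pigmented class (log2 fold change -4.87 ± 0.65). Stxbp5l (ENSMUSG00000022829, chromosome 16, 37114942 to 37384962) followed at -4.08 ± 0.58, then myosin light chain kinase (Mylk, -3.85 ± 0.51), complement component C2 (-3.80 ± 0.53) and the vesicle GTPase Rab3b (-3.48 ± 0.71). Tmem27 (-3.30), the homeobox factor Otx2 (-3.25), the receptor phosphatase Ptprz1 (-3.05), the GDNF receptor Gfra1 (-3.02) and Stra6, a receptor for retinol-binding protein (-3.00), completed the set. The pigmented class also carried Myh11, a marker of smooth muscle, at 322 and 203 CPM, against 8.47 and 7.77 CPM in the non-pigmented class. Without the Myh11-rich sub-cluster of the pigmented class, an alternative chosen after seeing the data, Hs3st1 stood at -3.86, behind Stxbp5l at -4.15, with Mylk at -3.23 and Rab3b at -2.50, each still past the threshold. In library 2 alone Hs3st1 (-3.39) lay behind Igfbp5, Stxbp5l, C2, Tmem27 and Slc4a4 (-4.02 to -3.47).

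In total, 352 genes were higher and 230 lower in non-pigmented epithelium, of 6991 tested (edgeR quasi-likelihood test on 36 summed profiles, Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1). All 582 had the same direction in each library, but they were called from these same libraries, so this is no separate check. Without the Myh11-rich sub-cluster the counts were 329 and 221. Of 73 genes that the naming rule selected for this comparison, 57 kept their call under every alternative that gave a test, whereas Abca1, Agrn, Bmp4, Hes1, Id1, Id2, Igfbp5, Lama2, Myoc, Npr3, Nr2f2, Pam, Rdh10, Slc4a2, Trf and Wls each lost it under at least 1. Pigmented cells were sequenced deeper, with medians of 5148 and 4089 UMIs per cell against 3192 and 2478. Of the 73 genes, 19 differed by at least 1 in log2 fold change between the libraries taken alone. Low counts bear on such gaps. In library 1 the pigmented class had 1 UMI of Aqp4 and 0 of Tmem132b and Col2a1, and the non-pigmented class had 1 of Hs3st1. The largest gaps were those of Aqp4 (6.35 in library 1 and 3.75 in library 2), Igfbp5 (-1.56 and -4.02), Tmem132b (6.61 and 4.20), Serping1 (1.77 and 4.01), Col2a1 (6.49 and 4.27), Cp (6.71 and 4.52) and Hs3st1 (-5.26 and -3.39).

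**Figure D2:**
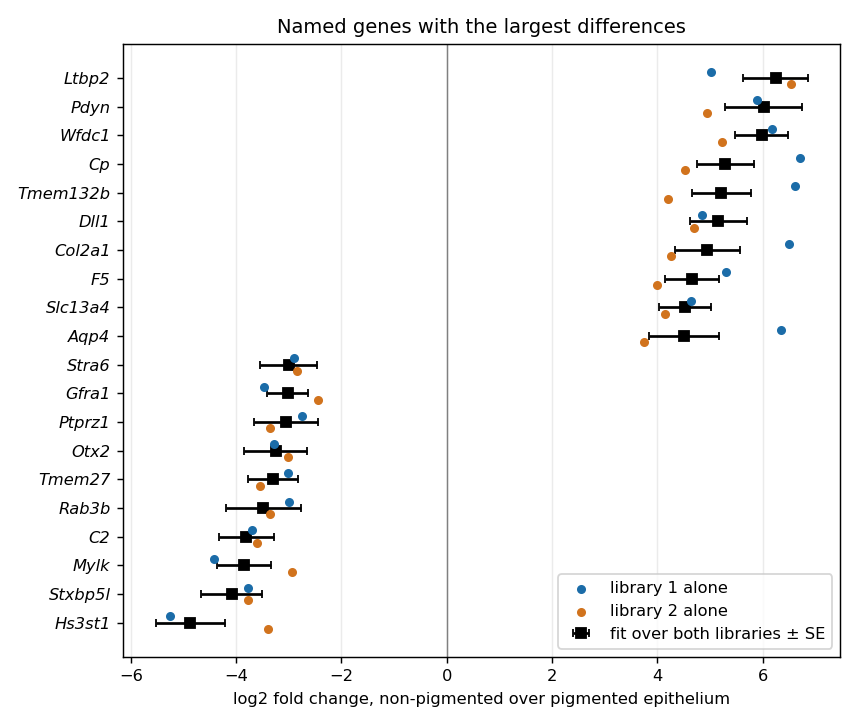
Log2 fold change of non-pigmented over pigmented epithelium (horizontal axis) for the 10 named genes with the largest difference in each direction. Black squares give the fit over both libraries with its SE as bars, and coloured points give each library alone. The fitted values run from Ltbp2 at 6.25 to Hs3st1 at -4.87. Each library lies on the same side of 0 for all of these genes, as the naming rule required.

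Called genes of the vitreous and zonular lists were more often higher than lower in non-pigmented epithelium. This holds between the layers only. Some members had the same highest class in both libraries, with at least 50 UMIs there. Of these, 4 vitreous genes were highest in fibroblasts and 2 in non-pigmented epithelium. For the zonular list it was 7 and 5, with 3 in the smooth muscle class. Of 12 measured genes of vitreous matrix and hyaluronan, 6 were higher and 0 lower (7 and 0 when adjusted over the list alone). They included Col2a1, fibulin 1 (Fbln1, 3.96 ± 0.57, at 2693 and 2603 CPM), Prelp (3.73 ± 0.54) and Col5a1 (3.43 ± 0.50). This list passed the set test (camera, preset correlation of 0.01, adjusted p = 1.52e-04) and had an adjusted p = 0.0674 with an estimated correlation. Over all alternatives its adjusted p ranged from 8.83e-07 to 0.0674. Of 25 genes of the zonule, microfibrils and elastic fibres, the suspensory fibres of the lens, 7 were higher and 2 lower (9 and 2 adjusted over the list alone). Beside Ltbp2, the fibrillins Fbn2 (4.37 ± 0.43) and Fbn1 (2.48 ± 0.43) and the microfibril protein Mfap4 (869 and 636 CPM against 131 and 57.3) were higher. The 2 lower genes had fewer than 50 UMIs per library, and 0 were called lower with a mitochondrial limit of 15%, with count splitting at resolution 2 or without the Myh11-rich sub-cluster. Over the whole list 14 of 25 log2 fold changes lay above 0. The list had an adjusted p = 0.0492, and an adjusted p = 0.561 with an estimated correlation, within a range from 0.0210 to 0.561 over the alternatives. Basement membrane genes went both ways, with 4 higher and 3 lower of 18, the same counts adjusted over the list alone. Col18a1, the gene of collagen XVIII, was higher (4.42 ± 0.36, at 1236 and 1315 CPM), as were Lamb2 (1.60) and Agrn (1.15), while Lama2 (-1.66) and Lamb1 (-1.53) were lower. That list did not pass the set test (adjusted p = 0.305).

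Junction genes passed the set test at the preset correlation (adjusted p = 1.90e-04) but not with an estimated correlation (adjusted p = 0.0674), nor with count splitting at resolution 2 (adjusted p = 0.0587), within a range from 7.10e-05 to 0.0674 over the alternatives. Of 21 measured, 7 were higher in non-pigmented epithelium and 2 lower, the same counts adjusted over the list alone. The claudins Cldn19 (3.48 ± 0.48) and Cldn2 (3.31 ± 0.44), the nectin gene Pvrl3 (2.59 ± 0.31) and the tight junction protein F11r (2.36 ± 0.33) were higher, and the nectin gene Pvrl1 was lower (-2.52 ± 0.39). Transport genes split between the layers: of 27 measured, 6 were higher and 4 lower (6 and 5 adjusted over the list alone), and the list did not pass the set test (adjusted p = 0.404). Among those higher in the non-pigmented layer were Aqp4, the taurine transporter Slc6a6 (3.45 ± 0.38) and the anion channel Best2 (3.29 ± 0.41). Among those higher in the pigmented layer were the bicarbonate cotransporter Slc4a4 (-2.93 ± 0.55), the sodium pump subunit Atp1b1 (-2.51 ± 0.47) and the anion exchanger Slc4a2 (-1.39 ± 0.39).

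Of 20 measured transcription factors of the eye, 5 were higher and 2 lower in non-pigmented epithelium (7 and 2 adjusted over the list alone). Six6 (3.94 ± 0.53) and Nr2f1 (3.61 ± 0.43) were higher, and Otx2 (-3.25 ± 0.59) and Nr2f2 (-1.22 ± 0.31) lower. The list had an adjusted p = 0.0242, and an adjusted p = 0.550 with an estimated correlation, within 0.00380 to 0.550 over the alternatives. Of 26 genes of BMP, TGF-beta, Wnt and Notch signalling, 4 were higher and 4 lower (5 and 6 adjusted over the list alone). Bmp4 (1.78 ± 0.43), Bmp7 (1.66 ± 0.33) and Hes1 (1.53 ± 0.47) were higher, and Id2 (-2.52 ± 0.47), the secreted Wnt modulator Sfrp1 (-2.16 ± 0.41), Id1 (-1.88 ± 0.42) and Wls (-1.37 ± 0.39) lower. That list did not pass the set test (adjusted p = 0.826). Its test direction was down while the median (0.33) and mean (0.13) of its log2 fold changes were above 0, and without Sfrp5, at 0 UMIs in pigmented epithelium and 2 in the non-pigmented class, the mean was -0.02.

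Complement genes counted 3 higher and 1 lower of 10 measured (5 and 1 adjusted over the list alone). Serping1, the inhibitor of C1 (2.87 ± 0.60), C4b (2.02 ± 0.42) and C3 were higher, and C2 was lower. The list had an adjusted p = 0.0242, and an adjusted p = 0.536 with an estimated correlation, within 0.0196 to 0.536 over the alternatives. The list of mitochondrial respiration and glycolysis lay lower in non-pigmented epithelium as a set (adjusted p = 0.0242, and an adjusted p = 0.550 with an estimated correlation, within 0.00147 to 0.550). Of its 25 genes, 0 were called lower by themselves and the glycolytic enzyme Eno1 was called higher (1.84 ± 0.32), with the same counts adjusted over the list alone. At the same time, the median mitochondrial share of UMIs per cell was 14.3% in pigmented and 11.5% in non-pigmented cells.

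The remaining lists did not pass the set test. For proteins of aqueous humour, 3 genes were higher, among them Cp and Enpp2 (2.63 ± 0.42), and 3 lower, among them the protease inhibitor A2m (-2.71 ± 0.53) and transferrin (Trf, -1.64 ± 0.45), of 18 measured (adjusted p = 0.407). Neuropeptide processing had 2 of 10 higher, among them the amidating enzyme Pam (1.81 ± 0.41), and 0 lower (adjusted p = 0.108). Antioxidant defence had 3 of 21 higher, namely the glutathione peroxidase Gpx3 (3.41 ± 0.51, at 3967 and 2300.4 CPM), Gstm1 (2.16) and Sod3 (2.10), and 1 lower, the glutathione synthesis gene Gclc (-1.79 ± 0.40; adjusted p = 0.774). Retinoid genes had 4 of 13 higher, among them the retinaldehyde dehydrogenase Aldh1a1 (4.39 ± 0.46) and Rdh10 (1.74), and Stra6 lower (adjusted p = 0.0777). Adjusted over the list alone, these 4 lists gave the same counts. Glaucoma-associated genes had 1 higher (Gas7) and 4 lower of 16, both ways of adjusting, the lower ones being Cyp1b1 (-2.44 ± 0.53), Myoc (-1.85), Optn (-1.84) and Abca1 (-1.43; adjusted p = 0.347 for the list). Myoc was at -1.17 in library 1 alone and -2.90 in library 2 alone, and its level in the pigmented class lay below that in T or NK cells, so it is within reach of free RNA. Optn was at 91.2 and 65.7 CPM in the pigmented class, below the 156 and 128 CPM of rods. Likewise, Trf of the aqueous humour list was at 237 and 314 CPM in the pigmented class, below the 536 and 690 CPM of macrophages. Receptors and enzymes of pressure-lowering drugs had 2 higher and 2 lower of 22 (2 and 3 adjusted over the list alone), among the lower ones the natriuretic peptide receptor Npr3 (-1.58 ± 0.41; adjusted p = 0.450 for the list). The dissociation response had 0 of 18 genes called either way, also when adjusted over the list alone (adjusted p = 0.897). Over the edgeR alternatives 0 to 3 of them were higher and 0 to 1 lower, and their median log2 fold change ran from -0.01 to 0.59.

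The fibroblast class, as a stand-in for the stroma, was compared with the mean of both epithelial layers. Log2 fold changes take that mean on the log scale, whereas ratios pool the UMIs of both layers. Clec3b, which encodes tetranectin (ENSMUSG00000025784, chromosome 9, 123150946 to 123157432), had 349 and 46.1 CPM in fibroblasts with 2303 UMIs in all, against 1 UMI in the epithelium, a ratio of 963 with a 95% counting interval from 173 to 38066. The chemokine gene Ccl11 had a ratio of 443 (79.3 to 17513), the dipeptidase gene Dpep1 461 (127 to 3805), the collagen gene Col14a1 247 (84.5 to 1201), Fibin 243 (43.4 to 9615) and Prg4, the gene of lubricin, 204 (36.4 to 8062). Apbb1ip and Lrrc32 had 0 UMIs in the epithelium and were at least 33.2-fold and at least 27.6-fold higher in fibroblasts, taking 3 counts in the epithelium as the floor. Apbb1ip was not specific to stroma, with 28.3 and 19.3 CPM in fibroblasts against 194 and 87.5 in T or NK cells and 128 and 90.4 in macrophages. The angiopoietin-like genes Angptl7 and Angptl1 had ratios of 182 (88.1 to 453) and 57.6 (29.1 to 134).

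In the other direction, Best2 (ENSMUSG00000052819, chromosome 8, 85007202 to 85014531) was at 112 and 124 CPM in the epithelium with 3 UMIs in fibroblasts, a ratio of 317 (108 to 1544). Slc13a4 had a ratio of 396 (109 to 3281), the neuropeptide S receptor Npsr1 219 (59.7 to 1820) and the monocarboxylate transporter Slc16a12 182 (49.4 to 1514). Log2 fold changes of fibroblasts over epithelium were -7.12 ± 0.72 for the homeobox gene Otx1, -6.82 ± 0.58 for the folate receptor Folr1, -5.94 ± 0.55 for Necab2, -5.93 ± 0.64 for the eye regulator Pax6, -5.77 ± 0.61 for F5 and -5.68 ± 0.54 for Lhx2. In total, 1019 genes were higher and 744 lower in fibroblasts, of 6991 tested by the same edgeR fit. Of these 1763, 1761 had the same direction in both libraries, from which they had been called. The excess of higher genes depended on the scaling, with 893 higher and 884 lower by RLE size factors and 813 and 859 by DESeq2.

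Each class was also compared with the mean of the other classes, taken on the log scale. Classes near 0 counts pull that mean down, so a log2 fold change can exceed the ratio of mean CPM. Defb11, for example, averaged 2.45 and 1.40 CPM over the other classes, and Best2 1.42 and 2.72. The clearest genes of non-pigmented epithelium were the beta-defensin gene Defb11 (126 and 181 CPM, log2 fold change 8.64 ± 0.46), Best2 (209 and 220.1 CPM, 8.57 ± 0.31) and F5 (224 and 223 CPM, 8.14 ± 0.33). In pigmented epithelium they were the glutathione transferase gene Gsta3 (1166 and 917 CPM, 6.55 ± 0.32), the substance P receptor Tacr1 (105 and 116 CPM, 6.54 ± 0.40) and the homeobox gene Gsx2 (78.3 and 42.6 CPM, 6.31 ± 0.47). Retinal pigment epithelium was set apart by Myrf (8.87), Serpine3 (8.78) and transthyretin (Ttr, 8.74, at 33948 and 43931 CPM), and melanocytes by the connexins Gjb6 (8.61) and Gjb2 (8.22) and the neuropeptide gene Cort (8.60). The fibroblast class had Angptl7 (8.01), Clec3b (7.77) and Dpep1 (7.71), and blood endothelium Cldn5 (10.45), Ptprb (10.40) and Eltd1 (9.93). The smooth muscle class had Chodl (7.73), the homeobox gene Lmx1b (7.29) and Nkain3 (7.22). Only 37 of its 306 and 16 of its 83 cells held a Myh11 UMI, so these genes need not be those of muscle cells. In all, 1115 genes were higher in non-pigmented epithelium, 1186 in pigmented epithelium, 1438 in fibroblasts, 1326 in retinal pigment epithelium, 1139 in melanocytes and 1210 in smooth muscle. Among the 12 other classes the count ran from 318 in B cells to 1515 in amacrine cells.

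Genes tied to glaucoma and to pressure-lowering drugs were spread over several classes. Myoc, the gene of myocilin, was at 2115 and 3063 CPM in the fibroblast class and at 101 and 126 CPM in pigmented epithelium. Trabecular meshwork markers also reached the naming minimum in the fibroblast clusters of 353 and 154 and of 353 and 347 cells. Levels in this class can therefore not be assigned to ciliary fibroblasts. T or NK cells also showed it, at 216 and 365 CPM, above the pigmented epithelium. Angptl7 was at 355 and 258 CPM in fibroblasts. Ednrb, the endothelin B receptor, was at 1953 and 1689 CPM in melanocytes, followed by blood endothelium at 191 and 128 CPM. Npr3 was highest in pigmented epithelium at 115 and 136 CPM. The kinases Rock1 and Rock2, targets of a class of pressure-lowering drugs, and Tmco1 and Atxn2 had no class that was highest in both libraries with 50 UMIs or more. Of the carbonic anhydrases, Car12 was highest in retinal pigment epithelium (453 and 295 CPM, against 6.44 and 7.69 in pigmented epithelium), as was Car14 (1534 and 1166 CPM, against 344 and 358 in pigmented and 257 and 319.8 in non-pigmented epithelium).

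**Figure D3:**
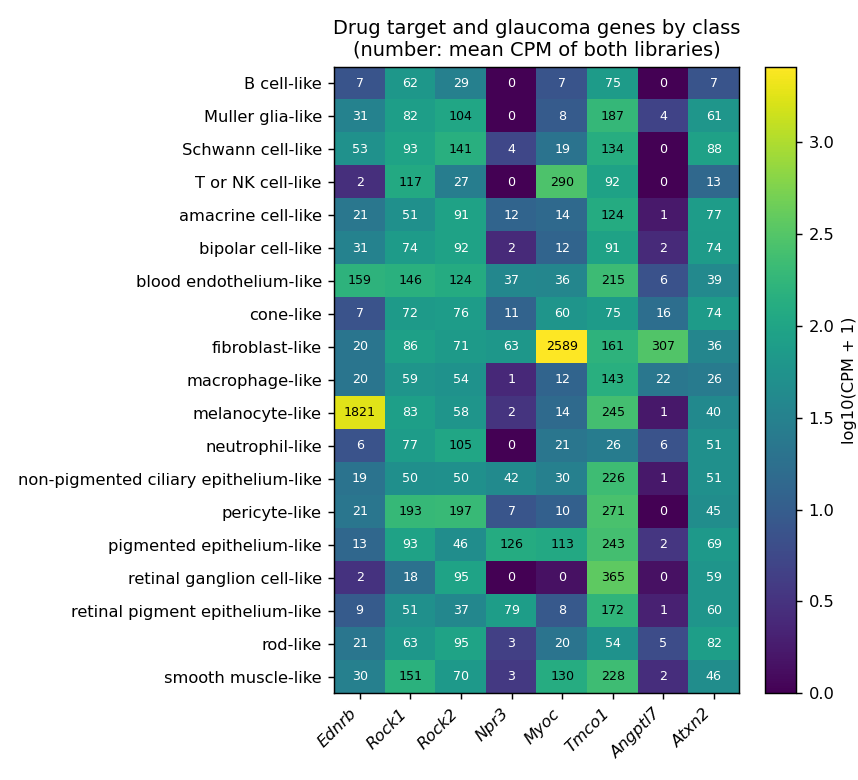
Mean CPM of both libraries (numbers, with log10 of CPM plus 1 as colour) for 8 drug target and glaucoma genes in each class. Myoc and Angptl7 peak in the fibroblast class and Ednrb in melanocytes, where single libraries reach 3063, 355 and 1953 CPM.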

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

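The count in this part was made only after the data had been seen. Of the barcodes that the cell filter removed, 139 of 903 in library 1 and 67 of 754 in library 2 had at least 50% of their UMIs from 4 globin genes, a signal in data that no comparison used. Among the kept barcodes 10 and 9 did.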

How the results depend on the processing

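The alternatives with the top 5% of Scrublet scores removed, with count splitting at Leiden resolution 2 and without the Myh11-rich sub-cluster were chosen after seeing the data. All others were fixed before. Where a value moved, the cause was not tested unless stated. Plain count splitting gave no value for the epithelial comparisons, since mast cells merged with the pigmented epithelium, which could then not be named. Clustering by library was applied to shares alone. With 1 library left out the fit had no residual degrees of freedom, so those values carry no test. In a simulation with these depths, 12% of genes changed 2-fold and 74% of genes changed 4-fold were recovered, so small differences were mostly out of reach. The changed genes there had a minimum mean count, so recovery may be lower for genes with fewer counts.

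For non-pigmented against pigmented epithelium, the genes higher in the non-pigmented class numbered 268 to 452 and those lower 157 to 348 over the alternatives. The value 348 came from a fit of the compared classes alone, which tested 4540 genes. Of the 582 called genes, 68.8% (count splitting at resolution 2) to 99.8% of those tested were called again, and 0 changed direction. For fibroblasts against epithelium the counts were 813 to 1292 higher and 608 to 973 lower, and 83.7% to 98.9% were called again. Lower genes outnumbered higher ones with DESeq2 alone (859 against 813). With the top 5% of Scrublet scores removed, 1 gene was called in the opposite direction. All 20 genes named there kept their call. Of the fold changes of single named genes over the alternatives, 1457 stayed, 66 moved and 58 lost the call. Genes higher in smooth muscle fell from 1210 to 705 with at least 1000 genes per cell. They fell to 684 at resolution 2 and 572 with count splitting at resolution 2. Several alternatives lacked classes in the fit. At resolution 0.5 these were smooth muscle, pericytes and T or NK cells. T or NK cells were also absent with doublets kept, the top 5% of Scrublet scores removed or no mitochondrial limit. Pericytes were also absent with those scores removed, at resolution 2 and with count splitting there. Neutrophils were absent with the stricter mitochondrial limit, clustering on all genes or count splitting at resolution 2. With at least 1000 genes per cell, pericytes, neutrophils and B cells were absent. With count splitting at resolution 2, the genes higher in a class numbered 183 in B cells, 224 in Schwann cells, 412 in T or NK cells and 686 in cones.

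Of 6 gene lists called, 0 remained with an estimated correlation, where the adjusted p was 0.561 for the zonule, 0.0674 for the vitreous and for junctions, 0.550 for transcription factors and for mitochondrial respiration, and 0.536 for complement. Size factors by RLE put the zonule at 0.0637 and no count filter at 0.0646. Without a replicate block the retinoid list passed at 0.0404. With the top 5% of Scrublet scores removed it passed at 0.0235, respiration missed at 0.0914, and the antioxidant (0.601) and BMP (0.802) lists turned upward. A mitochondrial limit of 15% left 3 lists called, with 0.148 for the zonule and for transcription factors, 0.284 for complement and a downward basement membrane list (0.779). No mitochondrial limit left 3, with 0.161 for the zonule, 0.127 for complement, 0.218 for respiration, and upward antioxidant (0.725) and BMP (0.873) lists. At least 1000 genes per cell left 3, with 0.0916 for the zonule, 0.212 for complement and for respiration, and upward antioxidant (0.672) and BMP (0.828) lists. Resolution 2 left 3, with 0.0746 for the zonule, 0.0589 for complement, 0.150 for respiration, and upward antioxidant (0.509) and BMP (0.920) lists. At resolution 0.5 the dissociation list turned downward (0.898). Clustering on all genes left 3, with 0.0630 for the zonule and for complement, 0.147 for respiration and an upward antioxidant list (0.801). Count splitting at resolution 2 left 2, with 0.0587 for the zonule and for junctions, 0.338 for complement, 0.145 for respiration, and upward antioxidant (0.775) and BMP (0.831) lists.

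With either library left out, the median difference of log2 CPM between the layers ranged from 0.55 to 0.63 for the zonule, 1.82 to 2.41 for the vitreous, 0 to 0.37 for basement membrane, 0.63 to 0.89 for junctions, -0.29 to -0.24 for antioxidants, 0.34 to 0.50 for retinoids, 0.73 to 0.76 for transcription factors, -0.81 to -0.24 for glaucoma genes, 0.99 to 1.86 for complement, -0.0375 to 0.22 for dissociation, 0.65 to 0.76 for neuropeptides, -0.48 to -0.25 for respiration and -0.29 to 0 for drug receptors. It changed sign for aqueous humour proteins (-0.22 to 0.71), transport (-0.05 to 0.08), BMP (-0.08 to 0.25) and dissociation (-0.0375 to 0.22).

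Shares moved beyond counting error as follows, library 1 before library 2. A mitochondrial limit of 15% gave non-pigmented epithelium 2.53% and 1.92%, pigmented epithelium 2.14% and 2.56%, and neural retina 22.6% and 60.9%. No mitochondrial limit gave pigmented epithelium 4.55% and 4.49%, and fibroblasts in library 2 9.45%. Fibroblasts took 34.0% and 11.8% with the top 5% of Scrublet scores removed, 29.99% and 14.6% with at least 1000 genes per cell, 34.7% and 12.1% at resolution 0.5, 33.1% and 12.4% with each library clustered on its own, 24.4% in library 1 with all genes, and 9.07% in library 2 with doublets kept. Neural retina took 23.0% and 59.5% with doublets kept (where 62 and 232 cells were unnamed and fewer were amacrine cells), 23.1% and 59.3% with the top 5% of scores removed, and 15.3% and 52.7% with at least 1000 genes per cell. The other 47 values stayed within counting error.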

Other observations

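All tests in this part, and the choice of the genes it names, were made only after the results had been seen. The fibroblast class consisted of 3 clusters, and list genes that took no part in the clustering differed between them, with values given here as CPM in library 1 and library 2. A cluster of 353 and 154 cells was high in Myoc (3539 and 5430), the secreted chaperone gene clusterin (Clu, 2451 and 1839), Cst3 (9385 and 10311), Angptl7 (662 and 683), Ltbp2 (369 and 299) and the elastic fibre gene Fbln5 (1051 and 891). A cluster of 353 and 347 cells was high in Igfbp5 (7050 and 7342), the nuclear receptors Nr2f1 (225 and 236) and Nr2f2 (176 and 184), the retinoic acid binding gene Crabp2 (210 and 222) and Foxc1 (232 and 345), and it also held Myoc (2015 and 2135). A cluster of 292 and 59 cells was high in the complement genes C3 (122 and 212), C2 (125 and 217), C1ra (297 and 465) and Serping1 (2235 and 2454), and in Mfap5 (1289 and 1200.4), with Myoc at 231 and 343. These differences were not tested.

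Levels of some further list genes by class follow. Foxc1 (307 and 388 CPM), a forkhead factor of the front of the eye, was highest in the class named smooth muscle. Tek, the receptor of the angiopoietins, was at 281 and 171 CPM in blood endothelium. Gja1, the gene of connexin 43, had 1188 and 1078 CPM in pigmented and 1003 and 766 CPM in non-pigmented epithelium, against 424 and 360.4 CPM in retinal pigment epithelium. Of 25 genes of mitochondrial respiration and glycolysis, 9 were highest in pigmented epithelium in both libraries, and that class was also the cluster with the highest median mitochondrial share of UMIs (14.3%, followed by 11.5% in the non-pigmented cluster).

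The sex of the mice is not in the labels. Xist, which female cells express, had 2 UMIs in library 1 and 50231 in library 2, where 82.4% of cells held it, whereas the Y-linked genes Ddx3y and Eif2s3y had 1405 and 1376 UMIs in library 1 and 0 in library 2. Pooling of both sexes in each library would need a sizeable share of cells with the other sex's RNA. At most 0.110% of the cells of a library had it, which argues against such a pool and is consistent with male eyes in library 1 and female eyes in library 2. Sex and library cannot be separated in this design.

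A sub-cluster of 55 cells in the pigmented class (41 and 14 cells) carried contractile genes beside pigment genes. It held Myh11 at 1028 and 2032 CPM, Mylk at 1385 and 1233, Smtn at 552 and 787, and the pigment gene Dct at 18182 and 11985. The sub-cluster was picked by its Myh11, so that level by itself decides nothing. A first comparison with the mean of the smooth muscle class was dropped, since single muscle cells can exceed a class mean. Droplets shared with a muscle cell would also bring the markers Cnn1, Des and Lmod1, at the share of muscle RNA that 8 contractile genes need, taken as at most 100%. For smooth muscle that share was 16.4% in library 1 and at the limit of 100% in library 2, and for pericytes 8.16% and 70.7%. With the Myh11-positive cells of the smooth muscle class as partners (37 of 306 cells and 16 of 83), the sub-cluster held 12.3% of the expected UMIs in library 1 (4 UMIs, 95% bootstrap interval over cells 0% to 27.1%) and 8.12% in library 2 (3 UMIs, 0% to 26.7%). With Myh11-positive pericytes (12 and 8 cells) it held 24.95% (0% to 44.4%) and 15.8% (0% to 40.1%). With these partners, the sub-cluster thus held fewer of these markers than the calculation asked for. A share of 100% cannot describe a droplet that also holds a pigmented cell. Cnn1, Des and Lmod1 were also clustering markers, so droplets rich in them may have joined other clusters. Shared droplets are therefore not excluded, nor are partners outside these classes. Free muscle RNA would reach both epithelial classes alike. A first comparison of the sub-cluster itself with the non-pigmented class was also dropped, since picking by Myh11 raises it. The whole pigmented class, without the later pick by Myh11, was compared with the non-pigmented class instead. Over the 8 genes, the median ratio was 2.91 in library 1 (95% bootstrap interval 1.69 to 18.3) and 8.14 in library 2 (4.38 to 16.7). Free RNA that reached both classes alike would give a ratio of 1, and both intervals lie above it. However, Myh11, Acta2 and Tagln were markers and thus among the clustering genes. They could take part in forming both classes, which may raise the ratio. The ratio alone can therefore not exclude such RNA as the source of these 8 genes. The interval of library 1 reaches below the bound of 2 set for this test. By that bound, free RNA that reached the classes unevenly stays open. Beside free RNA and shared droplets, with no biological explanation tested, a candidate explanation is a pigmented myoepithelial cell, such as the dilator of the iris. This is a hypothesis that these data alone cannot settle.

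Tyrp1, a pigment gene, had 732 and 438 CPM in the non-pigmented class, against 1797 and 1553 in the pigmented class, and free RNA or shared droplets may be the source. The ratio of Pmel to Tyrp1 UMIs in the non-pigmented class was 0.431 in library 1 and 0.808 in library 2. It lay below the 1.59 to 3.77 of rods, melanocytes and both pigmented epithelia. However, Pmel, Tyrp1 and Dct were markers and thus among the clustering genes. Droplets rich in Pmel or Dct may have joined pigmented clusters, which would bias this ratio and the comparison that follows. Neither can therefore exclude these sources. Whole pigmented cells in the class would leave its cells without Dct as poor in Tyrp1 as others. Of these, 47.7% and 31.9% had a Tyrp1 UMI (median depth 2678.5 and 1754 UMIs), against 7.87% and 13.8% of fibroblasts without Dct (5412 and 4870.5 UMIs). Macrophages of library 2 reached 19.7%, with an interval of 13.3% to 27.5% that overlaps the 21.2% to 44.2% of the non-pigmented cells. Low expression of Tyrp1 by non-pigmented cells themselves stays as a hypothesis that was not tested.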
